A study of Homo sapiens with 2 samples.

How the data were processed

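Gene expression was measured by messenger RNA sequencing in 2 libraries of the human bronchial epithelial line BEAS-2B, 1 with PBS and 1 with Dibifree at 500 µg/ml, and groups were taken from the treatment labels. The treatment protocol names Virofree, at 66.67 or 500 µg/ml for 4 h, and the labels name Dibifree; which product the time refers to is not settled by the sources. The lower dose and the STC-1 cells that the series description mentions were not analysed here. Per the labels' protocols, RNA was extracted with an RNeasy kit, libraries were made with a KAPA mRNA HyperPrep kit and sequenced in Illumina paired-end mode, and Trimmomatic 0.38 removed adapters and low-quality reads. Per the submitters' processing notes, HISAT2, HISAT, Bowtie2, featureCounts 1.6.3 and the genome build GRCh38 were used, with no role or order given. The strand setting, the treatment of reads with several matches and the annotation release are not given in the sources used here. The deposited counts are whole raw reads per Ensembl gene, without normalization. The deposited TPM values are scaled by the authors to gene length and to the same total in each library, per the file headers and the column sums. Dividing each deposited count by its TPM value gave the same relative gene lengths in both libraries.

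The depth was 16009800 reads in the PBS library and 18764822 reads in the Dibifree library. Gene identifiers were matched to GENCODE 29 on GRCh38, which held 58611 of the 58884 identifiers. It supplied gene types, exon overlaps and the 1-based coordinates, and this release may differ from the one the authors used. Gene symbols are those given with the deposited TPM values. Every row had an Ensembl gene identifier. Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 1.03 for PBS and 0.974 for Dibifree. The log2 ratio of Dibifree over PBS was taken after adding a prior count of 0.5. The 95% interval of each ratio was the exact Clopper-Pearson interval of the share of a gene's reads that fell in 1 library (scipy 1.17.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3). The main filter was a mean of at least 1 CPM, which left 12929 genes, holding 99.8% of the reads of each library. A gene was called higher or lower at a ratio of at least 2 in either direction with an interval that excluded equal levels. With 1 library per group, no p-value was computed. The 10000 random lists had the size of the fixed list and were drawn in 20 bins of mean expression, and a list needed at least 5 measured members to be placed. A list stood apart below the 2.5 or above the 97.5 percentile, and the counting interval of its median came from 1000 Poisson resamples. Genes are not independent replicates, so a percentile describes these libraries only.

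The rule, the lists and most alternatives were fixed before the data were examined. Genes named in the text are the 12 with the highest lower bound and the 12 with the lowest upper bound of the interval, up to 4 measured members of each list with the largest absolute log2 ratio, and the 5 with the highest mean TPM. Of these, 1 is not reported here. FN1 is named as the gene with most reads, and MT-RNR1, MUC5B, NFKBIA, ATF5 and ALDH18A1 were chosen after their values were seen. The 37 fixed lists cover stress, inflammation, lipid and glucose metabolism, mitochondria and ribosomes, cell cycle, matrix, clock, cell type and viral entry genes; 665 of their entries matched a gene and 1 did not. Of the lists, 32 had at least 5 measured members, and 1.6 would be expected outside the central 95% if members were drawn at random. Members of a list can vary together, so this number does not describe differences between single dishes. Markers of secretory, ciliated, blood, endothelial and enteroendocrine cells had too few measured members for a percentile.

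The calculation was tested on simulated data, with counts of every gene drawn from the real means and library sizes and 200 genes changed. The filter on expression left 12956 simulated genes. Of the changed genes, 50 at 3-fold, 50 at 4-fold, 47 at 0.25-fold and 50 at 1.5-fold passed the filter on expression. Of those that passed it, 100% were called at 3-fold, 4-fold and 0.25-fold, and 2% at 1.5-fold, which is below the threshold. Of the unchanged genes 0.172% were called, 95.4% of intervals held the true ratio, and 5 of 100 unchanged lists lay outside the central 95%. The simulation had Poisson error only, so it says nothing of the spread between cultures. The alternatives were scaling by total counts and by the median of ratios (DESeq2 1.42.0), the deposited TPM with pseudocounts of 1 and 0.1, no filter and a filter at 10 CPM, a prior count of 2, other size rules, random lists not matched on expression, and removal of a trend on gene length (statsmodels 0.14.6). Removal of a joint trend on GC content and length, and leaving out genes that share over 10% of their exon length, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.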

Results

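BEAS-2B is a line of human bronchial epithelial cells. Messenger RNA of these cells was sequenced after exposure to Dibifree, a dietary supplement, at 500 µg/ml, and in a control with phosphate-buffered saline (PBS). The labels give 1 library per group, so no spread between replicates can be had: no test was made, and every difference below is one between 2 libraries, with no replicate check. The written treatment protocol names a product called Virofree, at 66.67 or 500 µg/ml for 4 h, where the sample labels and the series title say Dibifree. Whether both names stand for 1 product is not stated, so the exposure time is known only from a protocol with another product name. The deposited counts summed to 16009800 reads in the PBS library and 18764822 in the Dibifree library, over 58884 genes. At least 1 read was counted for 22044 and 21624 genes, and at least 10 reads for 14119 and 14053. A count of 0 allowed up to 0.182 CPM (counts scaled to library size) in the PBS library and 0.164 CPM in the Dibifree library, taking 3 counts as the upper limit. All intervals and limits cover counting error only and treat reads as independent. Reads copied by PCR are not independent molecules, so the intervals may be too narrow. FN1, which encodes fibronectin, was the gene with most reads in both libraries, at 1.23% in PBS and 1.25% in Dibifree. The 10 genes with most reads held 5.91% and 5.57%. The 5 genes with the highest mean TPM (abundance scaled to gene length and library size) were the mitochondrial MT-CO2 and MT-RNR2, the actins ACTB and ACTG1, and TMSB10. MT-CO2 stood at 12769 TPM in PBS and 8867 TPM in Dibifree, while ACTB stood at 8669 and 8493 TPM. ACTG1 stood at 7589 and 8971 TPM, MT-RNR2 at 8201 and 6832 TPM, and TMSB10 at 7379 and 7278 TPM.

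The comparison of the Dibifree library with the PBS library addresses how airway epithelial cells respond to the supplement at the level of transcription. The Dibifree library held more transcripts of inflammatory cytokines, of the amino acid and integrated stress response driven by the factor ATF4, of immediate early genes and of cholesterol synthesis. It held fewer transcripts of the mitochondrial genome, of heat shock chaperones and of mitotic genes, and fewer of collagen I. Of 12929 genes with a mean of at least 1 CPM, 288 were at least 2-fold higher and 194 at least 2-fold lower, with a 95% exact (Clopper-Pearson) counting interval that excluded equal levels. The split depended on the settings, since scaling by total counts gave 239 and 237, no filter 382 and 477, a filter at 10 CPM 161 and 13, TPM with a pseudocount of 1 gave 200 and 59, and intervals wholly beyond 2-fold 146 and 18. Under the main rule the other 12447 met neither criterion, and the median log2 ratio over all tested genes was 0.01, with quartiles of -0.17 and 0.21. A difference of at least 4-fold was met by 32 higher and 7 lower genes. The higher genes were more abundant, with a median of 15.6 CPM against 1.84 CPM for the lower ones. Protein-coding genes made up 89.2% of the higher genes, 64.4% of the lower genes and 90.5% of the genes tested.

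**Figure D1:**
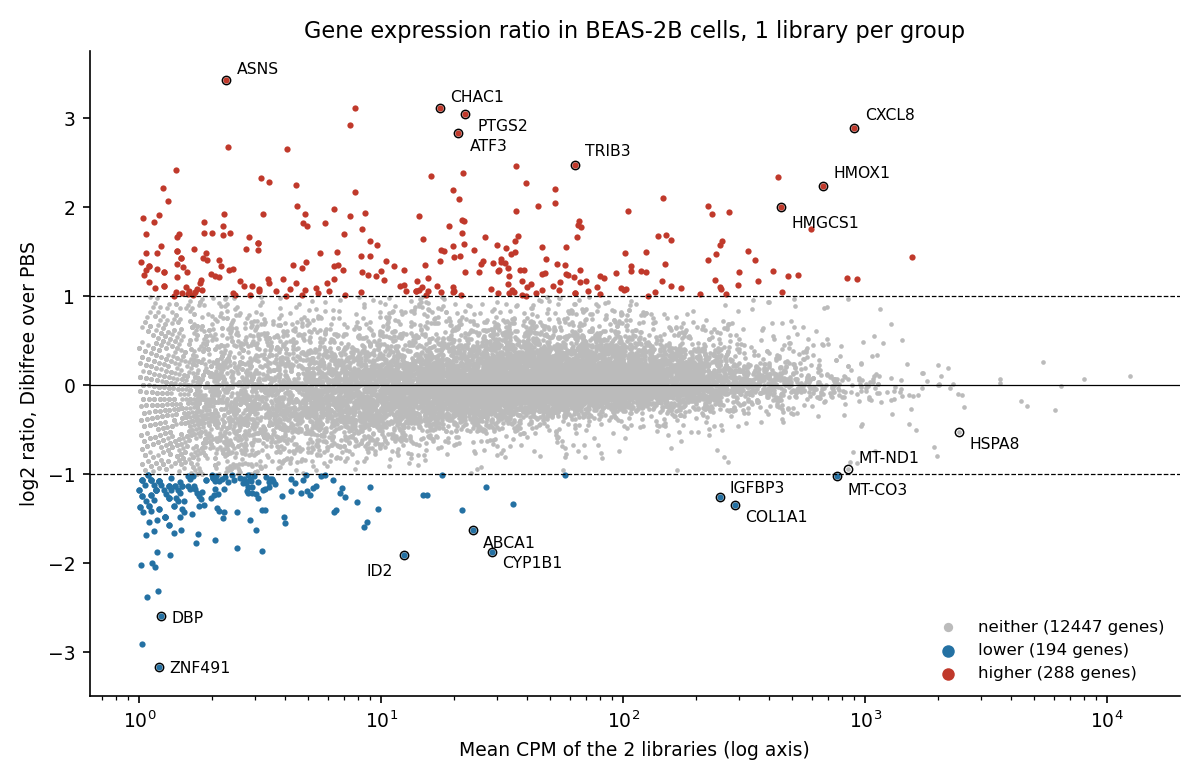
Log2 ratio of Dibifree over PBS for each of the 12929 tested genes (vertical axis) against its mean CPM in both libraries (horizontal log axis), with red points for the 288 higher genes, blue for the 194 lower genes, grey for the other 12447 and dashed lines at 2-fold. The higher genes reach abundant transcripts such as CXCL8 and HMOX1, while most lower genes sit near the left edge of the plot.

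The genes with the largest supported excess in the Dibifree library were led by CXCL8, which encodes the neutrophil chemokine interleukin-8 (ENSG00000169429, GRCh38 chromosome 4, 73740506 to 73743716). Its count was 3522 in PBS and 29000 in Dibifree, a 7.41-fold higher scaled level (95% counting interval 7.15 to 7.67). The gene of the glutathione-degrading enzyme CHAC1 (ENSG00000128965, chromosome 15, 40952962 to 40956519) had 59 and 572 reads, or 8.66-fold more in Dibifree (6.66 to 11.6). Both cyclooxygenase genes were among the leading genes. PTGS2 (ENSG00000073756, chromosome 1, 186671791 to 186680427) had 78 and 722 reads, and PTGS1 (ENSG00000095303, chromosome 9, 122370530 to 122395703) had 26 and 255. Their scaled levels were 8.28-fold (6.59 to 10.7) and 8.68-fold (5.88 to 13.8) higher. The stress-inducible transcription factor ATF3 was 7.15-fold higher (5.71 to 9.14), and the pseudokinase TRIB3, a product of the ATF4 response, was 5.57-fold higher (4.95 to 6.31). The cytokine gene IL1A was 5.54-fold higher (4.74 to 6.53). HMOX1, which encodes haem oxygenase, had 3856 and 20185 reads (ENSG00000100292, chromosome 22, 35380361 to 35394214) and was 4.71-fold higher (4.55 to 4.88). LURAP1L, with 28 and 240 reads, was 7.60-fold higher. Asparagine synthetase, ASNS, had 6 and 77 reads, and DDIT4, an inhibitor of the growth kinase mTOR, had 114 and 665. Both are uncertain. Another gene on the same strand overlaps 44.6% of the annotated exon length of ASNS, and one on the opposite strand overlaps 41.2% of that of DDIT4, where the strand setting of the counting is not known.

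Lower genes had fewer reads. CYP1B1, a cytochrome P450 of xenobiotic metabolism (ENSG00000138061, chromosome 2, 38066973 to 38109902), had 739 reads in PBS and 225 in Dibifree, a log2 ratio of -1.87 (95% counting interval -2.09 to -1.65). The transcription regulator ID2 (ENSG00000115738, chromosome 2, 8678845 to 8684453) had 321 and 95 reads, at -1.90 (-2.25 to -1.57). The cholesterol exporter ABCA1 (ENSG00000165029, chromosome 9, 104781002 to 104928237) had 593 and 214 reads, at -1.62 (-1.86 to -1.39). COL1A1, the main chain of collagen I (ENSG00000108821, chromosome 17, 50183289 to 50201632), had 6850 and 2989 reads, at -1.35 (-1.41 to -1.29). IGFBP3, which binds insulin-like growth factors, had 5791 and 2698 reads, at -1.25 (-1.32 to -1.19). The monocyte chemokine CCL2 had 210 and 77 reads and a log2 ratio of -1.59, in contrast to the other leading cytokines. The homeobox gene DLX3 had 83 and 25 reads, at -1.86. The other 5 genes at the lower end rested on 36 reads or fewer in PBS. They were ZNF491 with 36 and 4 reads, DBP with 35 and 6, JMJD7-PLA2G4B with 33 and 7, ZNF488 with 30 and 4, and ILDR2 with 30 and 6. JMJD7-PLA2G4B is a readthrough locus that shares 42.7% of its exon length with another gene, so its count is uncertain.

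Genes of the ATF4 response, which serves amino acid supply and the recovery from stress on translation, were higher as a group. All 23 measured members had a counting interval above 0, and 16 were at least 2-fold higher. The list's median log2 ratio was 1.23, with a counting interval of 1.20 to 1.36, above all 10000 random lists matched on expression. Its leading members were ASNS, CHAC1, ATF3 and TRIB3, all described above. Targets of the unfolded protein response of the endoplasmic reticulum differed less, with a median of 0.13 at percentile 90.4 of random lists. In that list HERPUD1 and XBP1 passed 2-fold, at log2 ratios of 1.23 and 1.09, followed by SDF2L1 at 0.73 and DNAJB9 at 0.72. Targets of p53 had a median of 0.28 at percentile 99.8, with 3 of 19 members at least 2-fold higher. The members went both ways, with 8 ratios below 0, 9 intervals above 0 and 1 interval below 0. BBC3, which encodes the cell death protein PUMA, had 19 and 105 reads (2.29), the growth arrest gene GADD45A stood at 1.35 and the stress cytokine GDF15 at 1.18. The cell cycle inhibitor CDKN1A stood at 0.98.

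The list of NF-kB targets and cytokines was higher as a group, with exceptions, and interferon-stimulated genes stayed inside the central range of random lists. The NF-kB and cytokine list had a median of 1.19, above all 10000 random lists, with 12 of 22 members at least 2-fold higher and 1, CCL2, lower. PTGS2, CXCL8 and IL1A led it, and CXCL2, a second neutrophil chemokine, followed with 86 and 489 reads at a log2 ratio of 2.35. The feedback inhibitor NFKBIA, chosen after its value was seen, stood at -0.01 (-0.13 to 0.11). Immediate early genes, which answer growth factor and stress signals within the first hours, had a median of 1.16, above all 10000 random lists, with 14 of 23 members at least 2-fold higher. The nuclear receptors NR4A3 and NR4A1 stood at 2.33 and 1.98, the phosphatase DUSP5 at 2.10 and the transcription factor EGR1 at 1.85. Interferon-stimulated genes had a median of -0.09 at percentile 38.1, with 6 of 13 intervals below 0 and 1 above. IFIT2, with 12 and 29 reads, stood at 1.09, while IFIH1 stood at -0.60 and IFI44 at 0.54, the last with an interval that spanned 0. IRF9 stood at -1.27 on 31 and 14 reads, and is uncertain because 48.4% of its exon length overlaps another gene.

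**Figure D2:**
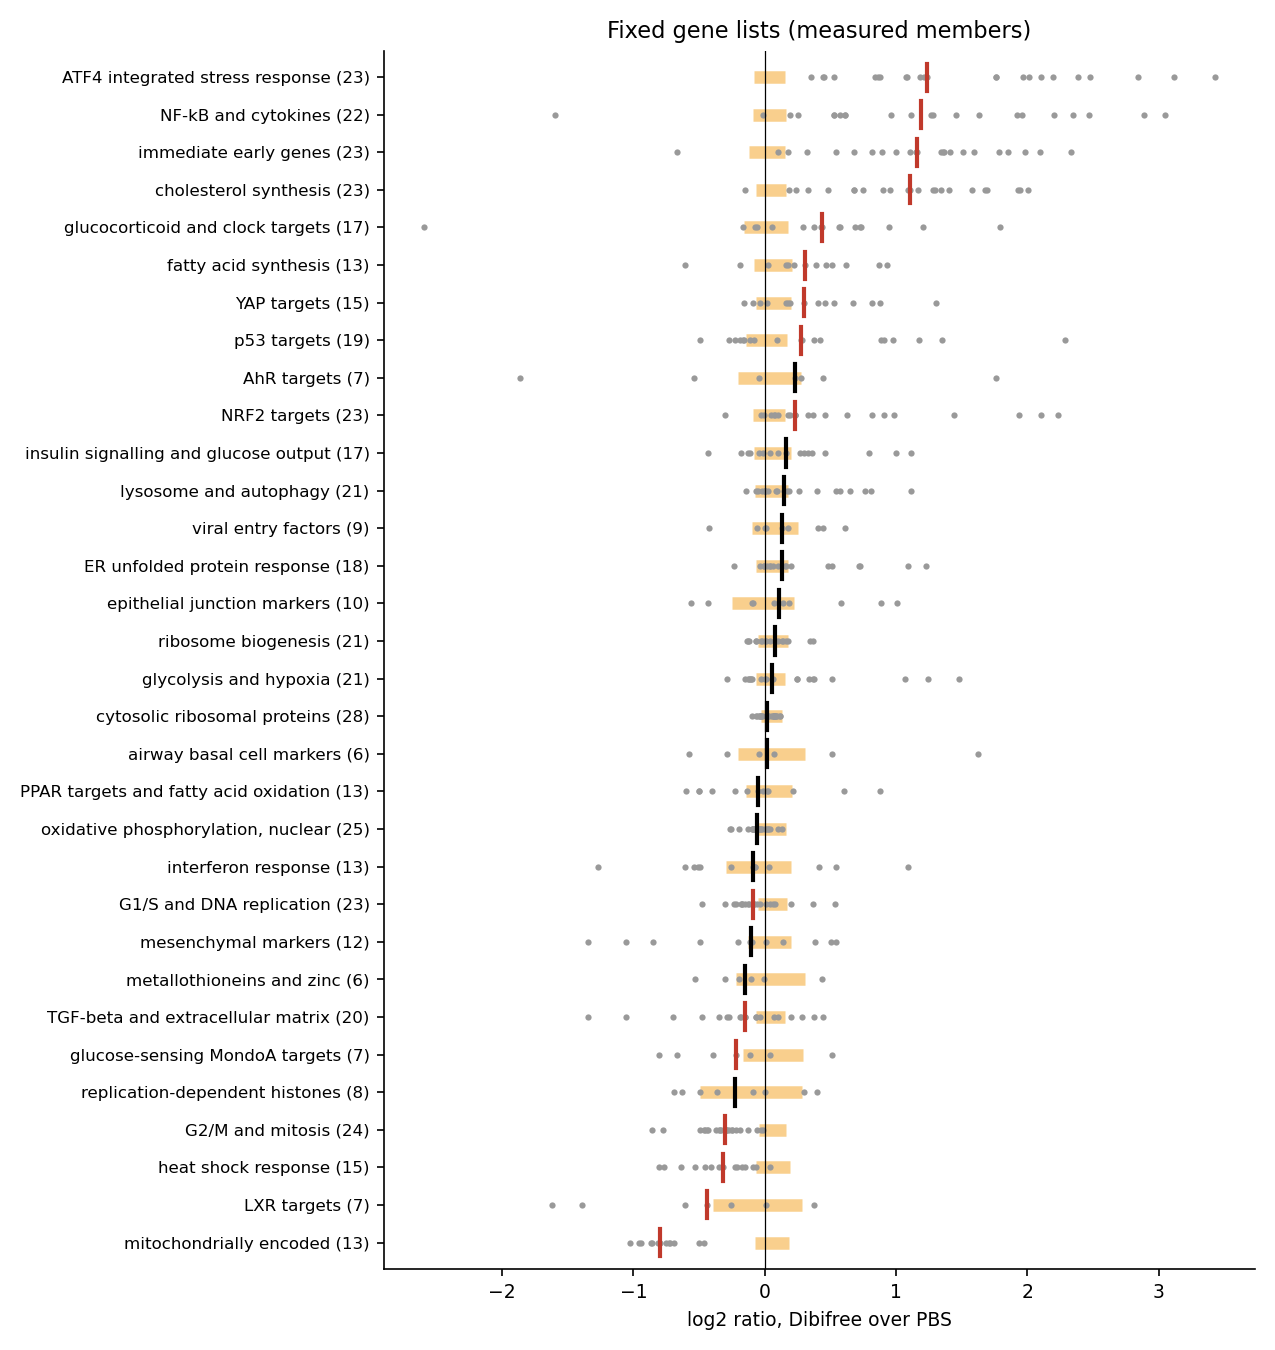
Log2 ratio of Dibifree over PBS (horizontal axis) for the fixed gene lists, one per line with the number of measured members in brackets. Grey dots are genes, vertical ticks are list medians (red where outside the central 95% of random lists, black otherwise) and orange bands show the central 95% of medians of random lists matched on expression; 9 lists lie above their band and 7 below.

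Oxidative stress genes under the factor NRF2 were slightly higher as a group, and a few of them strongly. Their median was 0.23 at percentile 99.9, with 17 of 23 intervals above 0 and 4 members at least 2-fold higher. HMOX1 led, the cystine transporter SLC7A11 stood at 2.10, OSGIN1 at 1.94 and the thioredoxin reductase TXNRD1 at 1.44 on 13854 and 41793 reads. SLC7A11 is also a member of the ATF4 list. Targets of the aryl hydrocarbon receptor moved apart. The median of that list was 0.23 at percentile 95.5, its mean was 0.04, and CYP1B1 at -1.87 lay opposite STC2 at 1.76, which is an ATF4 target too. TIPARP stood at -0.54 and the amino acid transporter SLC7A5, also in the ATF4 list, at 0.44. Of the 12 genes in the list of receptor targets, 3 are in another list, and its median is the value of one shared with the NRF2 list. Heat shock genes were lower, with a median of -0.32 below all 10000 random lists, and 13 of 15 members had an interval below 0, though none reached 2-fold. HSPA8, the constitutive HSP70 chaperone, had 47497 and 36633 reads (-0.53), and HSPA4L stood at -0.64. HSPA1A and HSPA1B stood at -0.80 and -0.76, but they are near-identical copies between which reads cannot be assigned with certainty. Metallothioneins and zinc transporters had a median of -0.15 at percentile 7.57. MT1E stood at -0.53 and the zinc importer SLC39A10 at 0.44, while the intervals of MT1F (-0.30) and MT1X (-0.20) spanned 0.

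Genes of cholesterol synthesis and uptake were higher, and some targets of the oxysterol receptor LXR were lower. The sterol list had a median of 1.10, above all 10000 random lists, and 13 of its 23 members were at least 2-fold higher. HMGCS1, which makes the precursor of mevalonate, had 2950 and 13178 reads, at a log2 ratio of 2.01 (1.95 to 2.07). The sterol oxidase MSMO1 stood at 1.95, the sterol sensor INSIG1 at 1.93 and the cholesterol carrier STARD4 at 1.70. LXR targets had a median of -0.44 at percentile 1.27, which became 3.02 without a filter, inside the central range. Of 7 measured LXR targets, 2 were at least 2-fold lower, 4 had an interval below 0 and 2 had a ratio above 0. Besides ABCA1, MYLIP, which degrades the LDL receptor, had 230 and 97 reads (-1.39), and the lipid regulator SREBF1 stood at -0.61. LPCAT3 stood at -0.44 and is uncertain, since 65.6% of its exon length overlaps another gene. Fatty acid synthesis genes had a median of 0.31 at percentile 99.8, and none of the 13 reached 2-fold. The desaturase SCD stood at 0.93, ACSS2 at 0.87 and FADS2 at 0.62, while SREBF1, also in this list, lay in the opposite direction at -0.61. Genes of fatty acid oxidation and PPAR signalling showed no shared direction, with a median of -0.05 at percentile 20.1. VLDLR stood at 0.88 and the lipid droplet gene PLIN2 at 0.61, against -0.60 for PDK4 and -0.50 for CPT2.

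Glucose metabolism differed in single genes more than as a programme. Glycolysis and hypoxia genes had a median of 0.06 at percentile 61.6, which became -0.02 under scaling by total counts. The glucose transporter SLC2A3 had 48 and 150 reads and was higher, and the angiogenic factor VEGFA stood at 1.24, NDRG1 at 1.07 and HK2 at 0.52. Insulin signalling and glucose output genes had a median of 0.16 at percentile 92.9. IRS2 stood at 1.12, the mitochondrial enzyme PCK2 at 1.00, FOXO3 at 0.80 and SIRT1 at 0.46. Targets of the glucose sensor MondoA had a median of -0.22 at percentile 0.81, a place outside the central range that was lost without a filter (2.70) and against unmatched random lists (4.11). TXNIP, which restrains glucose uptake, had 681 and 433 reads (-0.80). KLF10 stood at -0.67 and ARRDC3 at -0.39, with HK2 in the opposite direction.

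**Figure D3:**
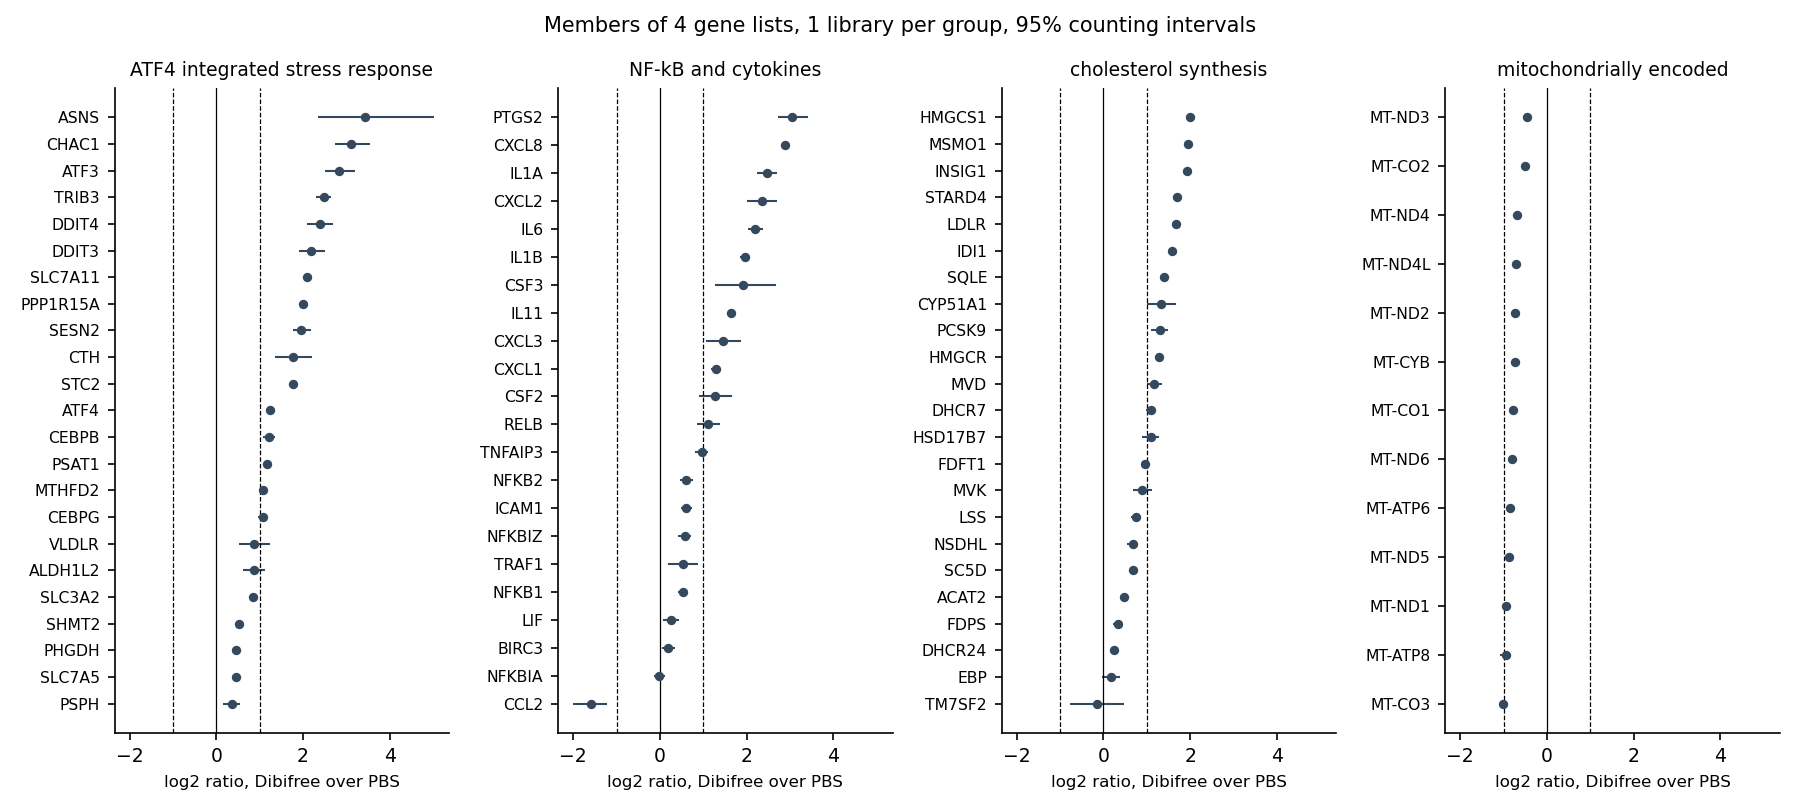
Log2 ratio of Dibifree over PBS for the measured members of the ATF4, NF-kB and cytokine, cholesterol synthesis and mitochondrially encoded lists, 1 panel per list; points are ratios and bars are 95% exact counting intervals of the 2 libraries. All 23 ATF4 members have intervals above 0 and all 13 mitochondrially encoded messenger RNAs have intervals below 0.

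Messenger RNAs encoded by the mitochondrial genome were lower, while nuclear genes of the same respiratory complexes differed little. All 13 had an interval below 0, and their median of -0.79 lay below all 10000 random lists. MT-CO3 had 16892 and 9245 reads, at -1.02 (-1.06 to -0.99), MT-ATP8 stood at -0.95, MT-ND1 at -0.94 and MT-ND5 at -0.87. Reads of mitochondrial genes made up 1.82% of the PBS library and 1.09% of the Dibifree library. The mitochondrial ribosomal RNA MT-RNR2 stood at -0.24. Part of these reads could not be separated from nuclear copies of mitochondrial DNA, because the handling of reads with several matches is not known. Nuclear genes of oxidative phosphorylation had a median of -0.06 at percentile 2.58, with NDUFS5 at -0.27, ATP5G3 at -0.20 and COX6A1 at 0.13, the last with an interval spanning 0. NDUFA1 stood at -0.26 with 44.5% of its exon length shared. Cytosolic ribosomal proteins had a median of 0.02 at percentile 27.1, with a sign that changed under total counts and under TPM. Their largest ratio was 0.12, for RPS12, followed by RPS3 at 0.11, RPL13 at 0.10 and RPS24 at -0.09. Ribosome biogenesis genes had a median of 0.08 at percentile 67.0, led by WDR43 at 0.37, RRP12 at 0.35, NOP16 at 0.18 and FBL at 0.16.

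Mitotic genes were lower, and replication genes differed less. The G2/M list had a median of -0.30, below all 10000 random lists, and 21 of 24 members had an interval below 0, though none reached 2-fold. The mitotic kinesin KIF20A had 5740 and 3518 reads (-0.86), HMMR stood at -0.49 and cyclin CCNB2 at -0.46. PRC1 stood at -0.78 on 62 and 40 reads, with 57.6% of its exon length shared with another gene. The G1/S and replication list had a median of -0.09 at percentile 0.24, or 7.63 against unmatched random lists, with 14 of 23 intervals below 0 and 3 above. The licensing factor CDT1 stood at 0.53 and E2F1 at 0.37, against -0.48 for cyclin CCNE1 and -0.31 for TYMS, which shares 39.1% of its exon length. Replication-dependent histones had a median of -0.23 at percentile 29.2. Of these, HIST1H2AC and HIST1H2AG stood at -0.69 and -0.49, and the intervals of HIST2H2BE (-0.63) and HIST1H1E (0.39) spanned 0. Histone messengers largely lack the poly(A) tail that the library kit selects.

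Extracellular matrix and TGF-beta genes were slightly lower as a group. Their median was -0.15 at percentile 0.02, with 11 of 20 intervals below 0 and 6 above. Beside COL1A1, COL1A2 had 141 and 75 reads (-1.06), COL5A1 stood at -0.70 and the TGF-beta inhibitor SMAD7 at -0.48. Targets of YAP were higher, with a median of 0.30 at percentile 99.8, led by ANKRD1 at 1.30, CTGF at 0.88, LATS2 at 0.81 and NUAK2 at 0.68. Glucocorticoid and clock targets had a median of 0.44, above all 10000 random lists. TSC22D3 stood at 1.79, the kinase SGK1 at 1.21 and NR1D1 at 0.95, whereas the clock output gene DBP stood at -2.59. Lysosome and autophagy genes had a median of 0.15 at percentile 94.5. The autophagy receptor SQSTM1 stood at 1.11, GABARAPL1 at 0.81, MAP1LC3B at 0.76 and WIPI1 at 0.65. Genes on the opposite strand overlap 20.7% of the exon length of SQSTM1 and 24.3% of that of WIPI1.

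Markers of secretory cells were nearly silent in both libraries, and markers of epithelial and mesenchymal state differed in single genes. Of 11 markers of secretory and goblet cells, 1 had any read, MUC5B, named here after its value was seen. Of 11 ciliated markers 6 had a read and 3 were measured, DNAH5 with 184 and 224 reads, CCDC40 with 29 and 35 and CAPS with 39 and 32, all with intervals of the ratio spanning 0. Basal cell markers had a median of 0.01 at percentile 47.6. Within them the keratin KRT17 had 2068 and 7090 reads (1.62), while ITGB4 stood at -0.57, LAMB3 at 0.51 and DLK2 at -0.29 with an interval spanning 0. Mesenchymal markers had a median of -0.11 at percentile 5.09. SNAI1 stood at -0.85 and ZEB2 at 0.54, next to the collagen genes already given. Epithelial junction markers had a median of 0.11 at percentile 86.0, with CLDN1 at 1.01, KRT19 at 0.88, ESRP2 at 0.58 and EPCAM at -0.56. Viral entry factors had a median of 0.13 at percentile 80.7, and none of the 9 measured reached 2-fold. ICAM1 stood at 0.61, ST6GAL1 at 0.44, HSPG2 at -0.42 and CTSL at 0.40. None of the blood cell markers was measured. Of the endothelial markers, CDH5 had 33 and 78 reads (1.08), and the intervals of KDR and TIE1 spanned 0. Of the enteroendocrine markers, SCG2 had 517 and 489 reads (-0.23), and PAX6 stood at -0.03 with an interval spanning 0.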

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

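Removal of the joint GC and length trend and leaving out overlapping genes were chosen after the data were seen; the other alternatives were planned. No called gene among those named and no list outside the central range changed its direction under an alternative. The balance of calls, however, turned over without a filter. The medians of the glycolysis, ribosomal protein, basal cell, AhR and nuclear oxidative phosphorylation lists, inside the central range, changed sign under at least 1 alternative. The lower genes numbered 194 and fell to 59 with TPM and a pseudocount of 1, where 200 were higher (77.2% of calls, against 59.8%), because the pseudocount shrinks low genes. Without a filter 477 were lower and 382 higher (44.5% of calls), since 24368 genes were then tested. With at least 10 CPM, 161 were higher and 13 lower. An interval wholly beyond 2-fold left 146 higher and 18 lower, and a 1.5-fold rule gave 793 and 562. Total counts gave 239 higher and 237 lower, with 50.2% of calls higher and a median of all genes of -0.07. The median of ratios gave 306 and 175, a prior count of 2 gave 276 and 165, TPM with a pseudocount of 0.1 gave 269 and 186, and leaving out overlapping genes gave 249 and 143. Removing the length trend gave 288 and 194, of which 278 and 183 were the same genes, and removing the GC and length trend gave 295 and 191, sharing 281 and 182. Dropping the interval from the size rule moved no call. The MondoA list left the outer range without a filter (percentile 2.70) and with unmatched random lists (4.11). The LXR list left it without a filter (3.02) and the G1/S list with unmatched random lists (7.63); the cause was not tested. The insulin list (99.4) and nuclear oxidative phosphorylation (1.93) entered it at 10 CPM, and the mesenchymal list (1.19) without a filter. The other 276 percentiles under alternatives kept their side, and 964 ratios of named genes stayed within their counting interval while 79 moved beyond it. Fewer than 40 reads in all lay behind 32 of the 194 lower and 9 of the 288 higher genes. Of the 482 called genes, 90 shared over 10% of their exon length with another gene.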

Other observations

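Tests of scaling, of mitochondrial recovery, of stress at harvest, of endoplasmic reticulum stress, of short-lived transcripts and of expression level were chosen after their results, or values close to them, were seen. Lists of further BMP targets, aminoacyl-tRNA synthetases, other ATF4 targets and other SREBP2 targets were written after the table of all genes was seen. Their members had not been looked at as a set, but ACLY, an SREBP2 target, was already in the fixed fatty acid synthesis list.

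The mitochondrially encoded messenger RNAs had a median log2 ratio of -0.79. The highest median under the other scalings was -0.76, and with the trend on GC content and length removed it was -0.68, so neither accounts for the whole difference. The mitochondrial ribosomal RNAs had a median of -0.37 (MT-RNR2 at -0.24, MT-RNR1 at -0.50), above the messengers' median. The messengers themselves ranged from -1.02 for MT-CO3 to -0.46 for MT-ND3. MT-RNR1 lies at the level of MT-CO2 and below MT-ND3, so the ribosomal RNAs did not stand apart as a class. The ratios differed by more than counting error, with intervals of -1.06 to -0.99 for MT-CO3, -0.54 to -0.38 for MT-ND3 and -0.26 to -0.22 for MT-RNR2. In these libraries that argues against an even loss of mitochondrial RNA as the only source. The handling of reads with several matches is not known, so nuclear copies may add to these counts. An even loss as a part of the difference stays open. Lower mitochondrial transcription or faster decay of the messengers may be part of it, as an untested hypothesis.

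The ATF4, NF-kB, immediate early and cholesterol lists were higher together, with 55 of their 91 distinct measured genes at least 2-fold higher. With the trend on GC content and length removed, the lowest of the 4 medians was 1.13. The heat shock list stood at -0.32, which argues against heat at harvest. Dissociation stress stays open, because immediate early genes, which answer stress signals, are among the 4 higher lists. A difference between single dishes cannot be told apart from an effect of Dibifree, since each group had 1 library. The effect of the supplement is therefore a hypothesis that needs further cultures.

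Genes that were lower included many non-coding genes of low level. Non-coding and protein-coding genes of 1 to 5 CPM had medians of -0.16 and -0.15, a difference of -0.0132. Their medians thus followed expression level rather than gene class. The calls differed more. At that level, 66 of 882 non-coding genes were lower and 30 higher, against 98 and 68 of 1586 protein-coding genes. A part of gene class in the excess of lower calls stays open. Reads on sense intronic genes had a log2 ratio of -0.0351 (-0.0984 to 0.0283), and the 49 tested ones had a median of -0.17, close to that of other genes of 1 to 5 CPM. The sum argues against a loss of unspliced RNA large enough for the 2-fold calls, and a smaller one stays open. Olfactory receptor genes had 32 and 39 reads, a log2 ratio of 0.13 (-0.58 to 0.85), too few to decide on genomic DNA in the PBS library.

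Further target lists were set against named regulators. Aminoacyl-tRNA synthetases had a median of 0.45 and other ATF4 targets 0.92, the lower of their percentiles being 99.99, which is consistent with transcription by ATF4. The lists share 2 genes, and ATF5 (-0.78) and ALDH18A1 (-0.15) went against them. The unfolded protein response list of the endoplasmic reticulum lay at percentile 90.4, so stress of that organelle stays open as its source. Other SREBP2 targets lay at percentile 99.9 with a median of 0.39, as activation of SREBP2 would predict. Of the 11 measured, 2 were at least 2-fold higher. Further BMP targets lay at percentile 14.3 with a median of -0.12 over members that went both ways, which leaves lower BMP signalling, a candidate explanation for ID2, undecided. The low ZNF491 and ZNF488 were not shared by their class, since the 410 measured ZNF genes had a median of 0.05. The class lay at percentile 100 of 2000 random lists, with 2 members at least 2-fold higher and 5 lower. A loss of short-lived transcripts shared by ZNF genes would place the class low, so these values argue against it for the class. For ZNF491 and ZNF488 alone such a loss stays open. The early gene list, at 1.16, cannot decide on it, because new transcription would hide a faster loss.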
